A study of Homo sapiens with 2 samples.

How the data were processed

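RNA from MDA-MB-231, a human triple-negative breast cancer cell line, was profiled by RNA-seq in 2 libraries. Per the labels, 1 library came from cells carrying a vector control and 1 from cells over-expressing YWHAB, which encodes the 14-3-3 beta adaptor protein. The labels name total RNA. Their protocol fields also hold text on inducing fat cell differentiation and on harvesting retinas. A retina is not a source of this line. Adipocyte and retina markers were included among the gene lists as a check, and their values are given in the Results. They cannot decide whether the fat cell text applies, because no library known to lack that treatment was available for comparison. The culture treatment and library kit given in those fields were therefore not taken as facts about these libraries.

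The authors deposited FPKM values (fragments scaled to gene length and to the total of the library) for 60774 Ensembl gene identifiers, per the labels of both columns. The submitters' processing notes name HISAT2 2.0.5 and the human build hg38. The read counter, the annotation release, the handling of strand and of reads that match several places, and any filter are not given in the sources used here. No scaling between the libraries beyond FPKM was applied to the main values.

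The fragments behind the values were worked out from the table. Within a library, low FPKM values multiplied by gene length step by the worth of 1 fragment, and this step gave totals of 12375999 fragments for the vector library and 13810668 for the YWHAB library. With these totals, the value pair of 26769 of the 26770 genes above 0 in either library was a whole count over a whole length, within a relative tolerance of 1e-12. Counts worked out in this way summed to 99.9% of each total. For 14.1% of the genes the length is a multiple chosen as nearest to the mean transcript length in GENCODE 29, so their fragment numbers depend on that choice. The ratio of the libraries does not depend on it, but the width of its interval does. YWHAB is such a gene, with a length of 1925 nt against a GENCODE mean of 1928 nt. Intervals of 95% for the ratio of the libraries are exact (Clopper-Pearson on the split of a gene's fragments). Copies made by PCR are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 fragments, which for a gene of 1 kb is 0.242 FPKM in the vector library and 0.217 FPKM in the YWHAB library.

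Symbols, gene classes and coordinates (GRCh38, the assembly that hg38 denotes) came from GENCODE 29, which held 96.2% of the identifiers. The difference of a gene is log2(FPKM + 1) in the YWHAB library minus that in the vector library, a scale that understates the change of low genes. Genes with a mean of at least 1 FPKM over both libraries were compared (13420 genes). With 1 library per group there is no replicate check, so no test was run and no p-value is given. Genes were named by size alone, with a difference of at least 1 in either direction called 2-fold.

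Before the data were examined, 36 gene lists were fixed: 14-3-3 genes, epithelial adhesion and keratins, mesenchymal state, matrix proteolysis, protease inhibitors, integrins, focal adhesion and actin motility, collagens and basement membrane, TGF-beta response, YAP and TAZ targets, ERK pathway output, immediate early genes, FOXO targets, apoptosis regulators, p53 targets, proliferation, interferon-stimulated genes, NF-kB cytokines and chemokines, antigen presentation, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, NRF2 targets, cytosolic ribosomal proteins, replication-dependent histones, housekeeping genes, reported YWHAB protein partners, and markers of breast luminal, breast basal, adipocyte, retina, leukocyte, and endothelial and fibroblast cells. For each list with at least 5 measured members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. That percentile describes these libraries and is not a test of the conditions. A list below the 2.5th or above the 97.5th percentile is said to stand apart.

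The rule for named genes was also fixed beforehand. It takes YWHAB and the other 14-3-3 genes, then the 15 highest and 15 lowest protein-coding genes with a mean of at least 1 FPKM and at least 5 FPKM in the higher library, and in each list up to 4 measured members with the largest absolute difference. Any other gene is said to be named after its values were seen. Exon overlap with other genes was computed from GENCODE 29. After the named genes had been seen, the share of each gene's transcript 50-mers (1 in 16 sampled) that also occur in a gene at another place in the genome was computed, to mark genes with near-identical copies.

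The 6 alternatives planned were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling both libraries to equal FPKM totals, setting the median log2 ratio of genes with a mean of at least 10 FPKM to 0, and protein-coding genes only. Another 4 were added after seeing the data: a lowess correction (fraction 0.3) for transcript length and GC content, random lists matched on length too, a counting interval that excludes equal levels, and at least 50 fragments over both libraries.

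The procedure was tested on simulated data made from the means and totals of these libraries, with counting error alone. Spread between dishes or library preparations was not simulated, so the shares below do not cover it. The 2-fold rule took 0% of 50 genes simulated with a 1.5-fold change, 97.9% of 48 genes with a 3-fold change, 95.7% of 46 genes with a 4-fold change and 100% of 45 genes with an 8-fold change. Of 13295 simulated unchanged genes 57 passed it, and of the 12106 with at least 50 fragments 0 did. Simulated counts were recovered for 100% of 24912 genes, with the true lengths given, so the choice of a length multiple was not tested. A simulated list of 25 genes shifted by 0.3 lay at percentile 100, and 6% of 200 unshifted lists fell outside the middle 95%. The genes of these lists were picked at random, so lists whose genes vary together were not covered. The length and GC correction took a simulated slope of 0.202 per doubling of length to -0.00237 over 13206 genes. That slope was simulated on the same length that the correction used, so removal of a trend with another length was not covered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.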

Results

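Gene expression was measured in MDA-MB-231 cells with a vector control and in MDA-MB-231 cells labelled as over-expressing YWHAB, with 1 library per group. The series title links YWHAB over-expression to reduced migration and invasion, so the comparison asks which genes differ between the libraries, with proteases, adhesion and motility genes of first interest. The vector library held 12375999 fragments and the YWHAB library 13810668. At least 1 FPKM was reached by 13561 genes in the vector library and 13312 in the YWHAB library. Across the 13420 genes compared, log2(FPKM + 1) correlated between the libraries with r = 0.977 (across genes, which are not independent replicates), and the median difference was 0.03. No value below has a replicate check, and differences between these 2 libraries are not shown to be differences between the conditions.

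YWHAB, the gene labelled as over-expressed, was at 239 FPKM in the vector library and 336 FPKM in the YWHAB library. The ratio was 1.41 (95% counting interval 1.36 to 1.45) from 5698 and 8939 fragments. The gene (ENSG00000166913) lies on chromosome 20 from 44885676 to 44908532 on the plus strand of GRCh38. Its direction matched the label, but its difference of 0.49 did not pass the 2-fold rule. Of the 500 genes nearest to YWHAB in mean FPKM, 24 (4.8%) were as far above the vector library, and 11% were as far in either direction. Over all genes compared 8.01% were as far above. The values count fragments over the whole gene, so transcript from the vector and from the chromosome cannot be separated here. Among the other 14-3-3 genes, which encode adaptor proteins that bind phosphorylated partners, SFN was at 71.5 and 87.8 FPKM in the vector and YWHAB libraries, YWHAH at 69.2 and 82.9, YWHAQ at 242 and 268, YWHAE at 784 and 861, YWHAZ at 762 and 819, and YWHAG at 54.5 and 51.4. None of the 7 genes passed the 2-fold rule. YWHAB made up 10.8% of their summed FPKM in the vector library and 13.4% in the YWHAB library. The median of the 14-3-3 list was 0.14, at percentile 83.3 of random lists. In 27 reported YWHAB protein partners the median was 0.10 (percentile 79.2) and 0 members passed the rule. The largest difference there was for IRS1, an insulin receptor adaptor, at 14.8 and 29.8 FPKM.

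More genes were 2-fold lower than 2-fold higher in the YWHAB library, though not among the longest transcripts. The lowest protein-coding gene in the main setting was MMP3, which encodes the matrix protease stromelysin-1. Over all 13420 genes, 92 were higher and 265 lower. The 95% counting interval of the ratio excluded equal levels for 60 and 235 of them. Among the 11518 protein-coding genes 34 were higher and 167 lower, and the counting interval excluded equal levels for all of these. The imbalance went with transcript length: in the shortest of 5 equal groups of protein-coding genes 5 were higher and 62 lower, but in the longest 16 were higher and 11 lower. After length and GC correction 103 genes were higher and 240 lower. Short RNA classes, which such libraries measure poorly, gave 38 of the higher and 31 of the lower genes.

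The highest protein-coding gene was MALL, a membrane raft protein, at 1.75 FPKM in the vector library and 12.9 in the YWHAB library (ratio 7.38, counting interval 5.16 to 10.9). FOS, a subunit of the AP-1 transcription factor, followed at 23.1 and 96.4 FPKM, and GRAMD1B, a sterol transfer protein, at 9.03 and 35.5 FPKM. PLEC, which encodes the cytoskeletal linker plectin, was at 60.8 and 181 FPKM, and FAM20C, a kinase of the secretory pathway, at 43.1 and 133 FPKM. The other genes among the 15 highest were TNFRSF11B (osteoprotegerin, ratio 4.01), NOX5 (an NADPH oxidase, 3.63), DMBT1 (4.07), NR4A2 (an orphan nuclear receptor, 3.40), SGK1 (a kinase, 2.75), SLCO4A1 (an organic anion transporter, 2.56), TYMS (thymidylate synthase, 3.22), SPRY1 (2.90), EDN2 (endothelin 2, 3.07) and PLXNA1 (a semaphorin receptor, 2.38). The exons of TYMS overlap ENOSF1 on the opposite strand over 39.2% of their bases, and the use of strand in counting is not given, so its value is uncertain.

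MMP3 was at 231 FPKM in the vector library and 4.79 in the YWHAB library (ratio 0.0208, counting interval 0.0158 to 0.0269). GDF15, a stress-induced cytokine, was at 71.4 and 4.09 FPKM, and SERPINB2, plasminogen activator inhibitor 2, at 106 and 14.9 FPKM. Other genes among the 15 lowest were FOLR3 (a folate receptor, 58 fragments in the vector library and 1 in the YWHAB library), GPNMB (a membrane glycoprotein, 8.46 and 0.637 FPKM), DPP4 (a cell surface peptidase, 9.08 and 0.761), MMP10 (5.52 and 0.371) and DDIT3 (the stress transcription factor CHOP, 85.8 and 17.4). DDIT3 shares 27.2% of its exon bases with MARS on the opposite strand. The remaining 7 of the 15 lowest have close relatives that can share reads, so how fragments were split among relatives is uncertain. These were HIST2H2AA4 (253 and 1 fragments), HIST2H4B (88 and 4), XAGE1B (231 and 14), SERF1B (127 and 3), PSG2 (119 and 3), PSG4 (432 and 39) and PSG9 (322 and 31). The near-identical copy of HIST2H2AA4, HIST2H2AA3, had 3 and 2 fragments, that of SERF1B, SERF1A, had 6 and 6, and that of XAGE1B, XAGE1A, had 22 and 17.

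**Figure D1:**
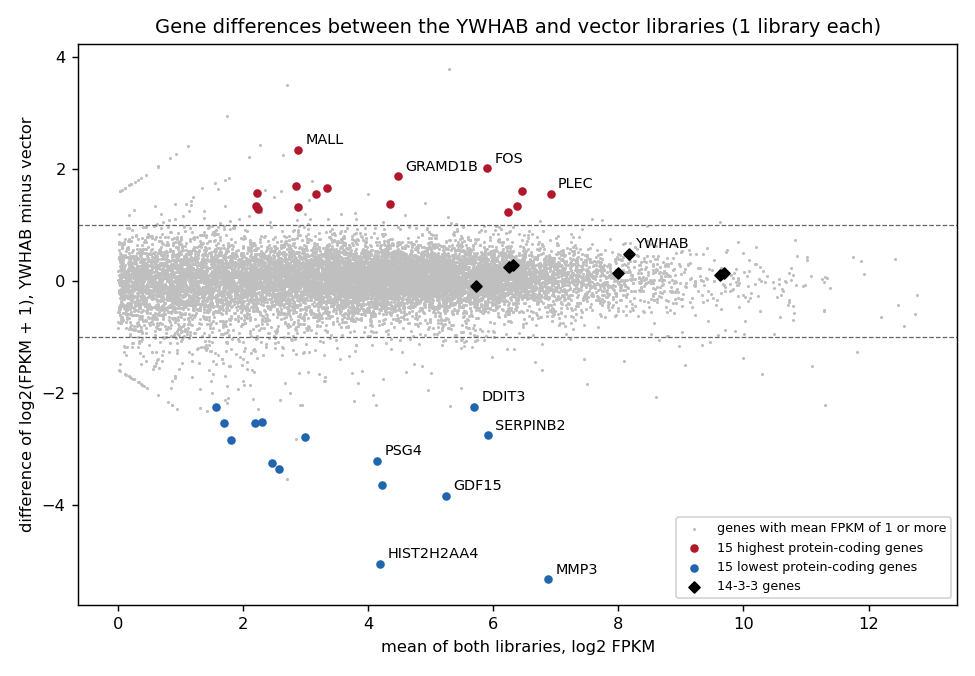
Each point is a gene with a mean of at least 1 FPKM. The horizontal axis is the log2 of its mean FPKM and the vertical axis its difference of log2(FPKM + 1), YWHAB minus vector, with dashed lines at the 2-fold rule; MMP3 lies lowest at -5.32, and YWHAB lies inside the lines at 0.49.

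The matrix proteolysis and protease inhibitor lists stood apart below random lists, with several collagenases and stromelysins among the 2-fold lower genes and most members not past the rule. Of 29 measured matrix proteolysis genes 6 were 2-fold lower and 0 higher, with a median of -0.15 (percentile 1.62), and the list stood apart. MMP1, interstitial collagenase, was at 4158 FPKM in the vector library and 894 in the YWHAB library, and MMP19 at 15.9 and 3.90. MMP3, MMP10, MMP13 (2.00 and 0.326 FPKM) and MMP9 (5.81 and 2.201 FPKM) made up the rest, the last pair named after their values were seen. For 5 of the 29 the counting interval lay above equal levels, and ADAM19, a membrane protease named after its values were seen, was at 32.5 and 55.7 FPKM. MMP19 overlaps TMEM198B on the opposite strand over 17.4% of its exon bases. Of 19 protease inhibitors 3 were 2-fold lower and 0 higher: SERPINB2, TFPI2 (an inhibitor of serine proteases, 630 and 149 FPKM) and SLPI (4.88 and 0.850 FPKM). Their median of -0.36 lay at percentile 0, and CST1, a cystatin, was at 71.1 and 35.7 FPKM. TIMP3, an inhibitor of metalloproteases named after its values were seen, was at 38.5 and 65.7.

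The epithelial and mesenchymal lists did not stand apart in the main setting. Among 20 epithelial adhesion and keratin genes CLDN1, a tight junction claudin, was the 1 member 2-fold lower, at 19.0 and 6.91 FPKM. The median was -0.15 (percentile 3.58) and turned to 0.00261 over members with a mean of at least 5 FPKM, while the list crossed to percentile 0.96 after length and GC correction, 0.74 with no filter and 2.09 with rescaling to equal totals. CLDN7 was at 38.6 and 22.5 FPKM, and ELF3, an epithelial transcription factor, at 1.60 and 0.575. In the 22 mesenchymal genes 0 passed the rule and the median was -0.04 (percentile 23.1). That sign turned over members with a mean of at least 5 FPKM (0.06, percentile 67.5) and with rescaling to equal totals (0.00325), while the median was -0.12 (percentile 2.51) after length and GC correction, and length matching gave percentile 8.73. SPARC, a matrix glycoprotein, was at 9.56 and 5.02 FPKM, the receptor kinase AXL at 453 and 668, the hyaluronan receptor CD44 at 697 and 998, and vimentin (VIM) at 736 and 861. Epithelial cadherin CDH1 had 3 and 0 fragments, and CDH2 and TWIST1 were listed at 0 in both libraries.

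The basement membrane list stood apart above random lists, while integrins and motility genes did not stand apart. Of 25 collagen and basement membrane genes 2 were 2-fold higher and 0 lower, with a median of 0.33 (percentile 100). The higher ones were COL6A3, a collagen VI chain, at 4.27 and 10.3 FPKM, and LAMA5, a laminin chain, at 135 and 289 FPKM. HSPG2 (perlecan) was at 121 and 208 FPKM, whereas LAMA4 was at 37.4 and 22.6. Long transcripts were in general slightly higher in the YWHAB library. The median difference was 0.12 in the longest of 5 equal groups of protein-coding genes and -0.06 in the shortest. After correction for length and GC content the list lay at percentile 99.7, but COL6A3 (0.94) and LAMA5 (0.96) then fell short of the 2-fold rule. The length is a mean over annotated transcripts (1640 nt for LAMA5), so a trend with the length of the transcripts expressed may remain in this list. Of 15 integrins ITGA7 (3.74 and 1.04 FPKM) was the 1 member 2-fold lower. ITGB4 was at 64.8 and 116 FPKM. The integrin median was 0.04 (percentile 56.0), with a mean of -0.02, and it turned negative with the median ratio of genes of at least 10 FPKM set to 0 and after length and GC correction. Among 62 focal adhesion and actin motility genes the 1 member past the rule was FSCN1, the actin bundler fascin, at 28.1 and 13.2 FPKM, and the median was 0.08 (percentile 83.3). Non-muscle myosin MYH9 was at 1356 and 2251 FPKM and filamin A (FLNA) at 930 and 1424.

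The unfolded protein and amino acid stress list stood apart below random lists. Of 29 members 8 were 2-fold lower and 0 higher, and the median was -0.44 (percentile 0). HSPA5, the main chaperone of the endoplasmic reticulum, was at 1908 FPKM in the vector library and 602 in the YWHAB library (ratio 0.315, counting interval 0.312 to 0.320). HERPUD1, which acts in degrading misfolded proteins, was at 283 and 78.1 FPKM, DDIT3 at 85.8 and 17.4, and ATF3, a stress transcription factor, at 22.9 and 5.72. The list was not uniform: ATF4 was at 155 and 157 FPKM, and PSAT1 and PHGDH, enzymes of serine synthesis, were at 34.5 and 56.2 and at 1.81 and 3.63 FPKM, all 3 named after their values were seen. Of 17 heat shock genes 0 passed the rule, with a median of 0.01 and a mean of -0.07 (percentile 42.8), and the median turned negative with the median ratio set to 0 and with no filter. HSPA1B was at 34.2 and 19.7 FPKM and HSP90AA1 at 1808 and 2352. HSPA1A and HSPA1B are near-identical, so their split is uncertain.

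**Figure D2:**
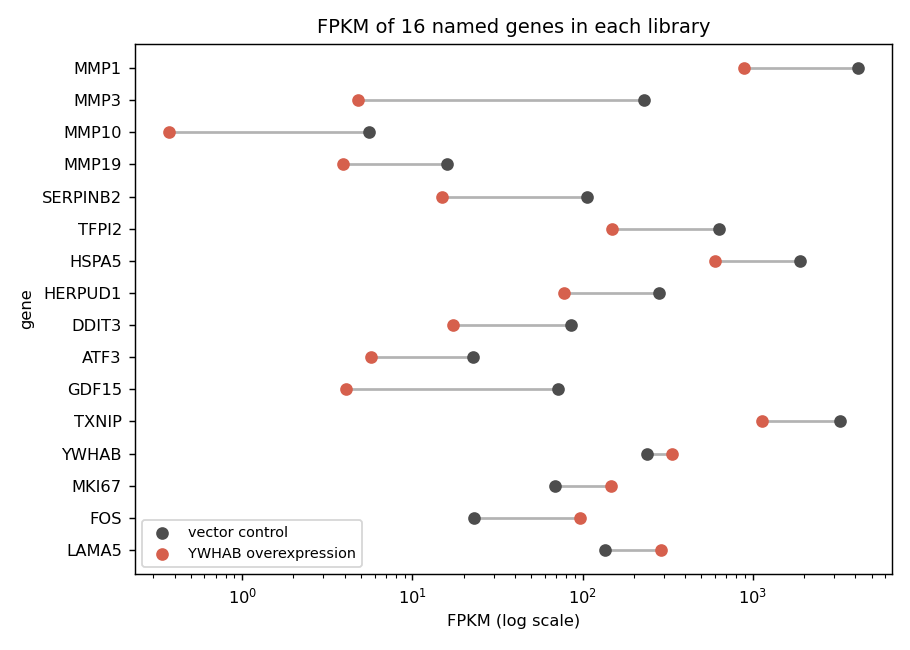
FPKM on a log axis for 16 named genes, with a dark point for the vector control library and a red point for the YWHAB library. MMP3 spans 231 to 4.79 FPKM, and YWHAB spans 239 to 336 FPKM.

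The proliferation list stood apart above random lists. Of 39 members 3 were 2-fold higher and 0 lower, and the median was 0.39 (percentile 100). The counting interval lay above equal levels for 33 and below for 1. Intervals that exclude equal levels were common in other lists too, with 10 of 26 housekeeping genes above and 9 below. MKI67, the Ki-67 antigen, was at 68.8 and 146 FPKM in the vector and YWHAB libraries, UHRF1, which maintains DNA methylation, at 23.9 and 53.8, TYMS at 2.19 and 7.05, and the replication helicase subunit MCM6 at 29.3 and 56.3. After length and GC correction MKI67 (0.96) fell short of the rule. The replication-dependent histone list stood apart below, with 6 of 6 measured members 2-fold lower and a median of -1.71 (percentile 0). Of the 38 names listed only 19 were matched to a gene, and 6 of these were measured. These 6 do not speak for the other names and do not count against the higher proliferation genes. The linker histone gene HIST1H1C was at 49.8 and 12.2 FPKM, HIST1H2BD at 20.9 and 5.97, HIST1H2BC at 7.36 and 1.30, and HIST2H2BE at 6.74 and 1.25. Most histone transcripts lack a poly(A) tail, and histone genes share sequence, so their values are uncertain. The list of p53 targets stood apart below, with 3 of 24 2-fold lower, 0 higher and a median of -0.22 (percentile 0.15). They were GDF15, SESN2 (a stress-induced sestrin, 11.4 and 4.10 FPKM) and the growth arrest gene GADD45A (57.4 and 26.7 FPKM). With no filter the p53 list lay at percentile 3.26. Among 30 apoptosis regulators 0 passed the rule and the median was -0.05 (percentile 11.9). The survival gene MCL1 was at 307 and 473 FPKM and BCL2A1 at 10.9 and 5.56.

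The NF-kB, interferon and antigen presentation lists stood apart below random lists, though most of their members did not pass the 2-fold rule. Of 29 NF-kB cytokine and chemokine genes 6 were 2-fold lower and 1 higher, with a median of -0.17 (percentile 0.16). The chemokine CCL20 was at 22.9 and 4.44 FPKM, and the cytokines IL24 at 165 and 54.0, IL32 at 104 and 44.6 and IL1A at 50.2 and 22.2. The 1 higher member, CSF3, was at 27.6 and 57.1 FPKM and the chemokine CXCL1 at 67.9 and 121, both named after their values were seen. For 9 of the 29 the counting interval lay above equal levels. Of 41 interferon-stimulated genes 1 was 2-fold lower and 0 higher, and the median was -0.26 (percentile 0). OASL was at 62.4 and 26.8 FPKM, OAS1 at 4.52 and 1.87, IFI44 at 45.5 and 23.2, and IFI6 at 11.2 and 5.64. Antigen presentation genes had a median of -0.18 over 23 members (percentile 0.87) and 0 past the rule. B2M, the light chain of class I molecules, was at 1077 and 590 FPKM, and HLA-B at 1213 and 655, the latter uncertain because HLA genes share sequence. PSMB10 was at 5.15 and 9.41 FPKM.

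The cholesterol synthesis, NRF2 target and mitochondrially encoded lists stood apart below random lists and the glycolysis and hypoxia list above, though few members passed the 2-fold rule. Of 23 cholesterol synthesis genes 2 were 2-fold lower and 0 higher, with a median of -0.35 (percentile 0): MSMO1, a sterol oxidase, at 91.2 and 34.9 FPKM, and STARD4, a sterol carrier, at 77.7 and 37.0. After length and GC correction STARD4 (-0.94) fell short of the rule. HMGCS1 was at 23.0 and 11.7 FPKM. Of 23 NRF2 targets 2 were 2-fold lower and 0 higher, with a median of -0.28 (percentile 0.04). These were FTL, the ferritin light chain, at 5080 and 2123 FPKM, and AKR1C1 at 15.8 and 4.09, which has close relatives that can share its reads. HMOX1, heme oxygenase 1, was at 40.0 and 20.1 FPKM. Of 13 mitochondrially encoded genes MT-ATP8 (148 and 53.5 FPKM) and MT-ND3 (888 and 400 FPKM) were 2-fold lower, and the median was -0.54 (percentile 0). Both genes are short (207 and 346 nt). MT-ATP8 shares 22.2% of its exon bases with MT-ATP6 on the same strand (2956 and 2033 FPKM), so its value is uncertain. MT-ND3 (-0.98) fell short of the rule after length and GC correction. Mitochondrial transcripts took 5.21% of the fragments in the vector library and 3.42% in the YWHAB library. In 37 nuclear genes of oxidative phosphorylation 0 passed the rule and the median was -0.09 (percentile 2.51). That list crossed to percentile 0.81 with a mean of at least 5 FPKM, 1.24 with a pseudocount of 0.1, 1.56 in protein-coding genes, 2.07 with rescaling to equal totals and 2.18 with the median ratio set to 0, but lay at 11.5 after length and GC correction and 28.6 with length matching. COX7C was at 217 and 157 FPKM. The 76 cytosolic ribosomal protein genes had 0 past the rule and a median of -0.08 (percentile 0.87). These transcripts are short, and the percentile was 15.95 against random lists matched on length too and 3.24 after length and GC correction. RPL27 was at 937 and 664 FPKM. In 35 glycolysis and hypoxia genes 1 was 2-fold lower, ANGPTL4 at 61.0 and 29.3 FPKM, yet the median was 0.19 (percentile 99.7). HK2, hexokinase 2, was at 21.8 and 34.7 FPKM.

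Signalling outputs were mixed. Of 25 YAP and TAZ targets 1 was 2-fold lower, GADD45A, but the median was 0.34 (percentile 100). FJX1 was at 14.7 and 25.1 FPKM and DOCK5 at 33.8 and 52.7, while IGFBP3 was at 42.3 and 23.3. FOXO targets had 3 of 24 members 2-fold lower, namely TXNIP (a thioredoxin inhibitor, 3245 and 1136 FPKM), GADD45A and SOD2 (201 and 97.04 FPKM). Their median of -0.13 lay at percentile 2.30, but at 4.33 over members with a mean of at least 5 FPKM and at 2.56 with the median ratio set to 0. DEPP1 was at 38.4 and 76.9 FPKM and shares 23.3% of its exon bases with RASSF4 on the opposite strand. In 22 ERK pathway genes SPRY1 was the 1 member 2-fold higher, and the median was 0.06 (percentile 58.3). The phosphatase DUSP4 was at 77.6 and 145 FPKM, its relative DUSP5 at 188 and 96.9, and CCND1 (cyclin D1) at 549 and 821. Of 22 immediate early genes FOS and NR4A2 were 2-fold higher and ATF3 lower, with a median of -0.02 and a mean of 0.05 (percentile 24.3). The 28 TGF-beta response genes had a median of -0.04 and a mean of 0.06 (percentile 16.5). PMEPA1 (6.83 and 16.9 FPKM) was the 1 member past the rule, and THBS1, thrombospondin 1, was at 236 and 465 FPKM. After length and GC correction the TGF-beta list lay at percentile 1.22. In 26 housekeeping genes 0 passed the rule and the median was -0.03 (percentile 21.3), a sign that turned with rescaling to equal totals and after length and GC correction. ACTB was at 2947 and 3945 FPKM.

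**Figure D3:**
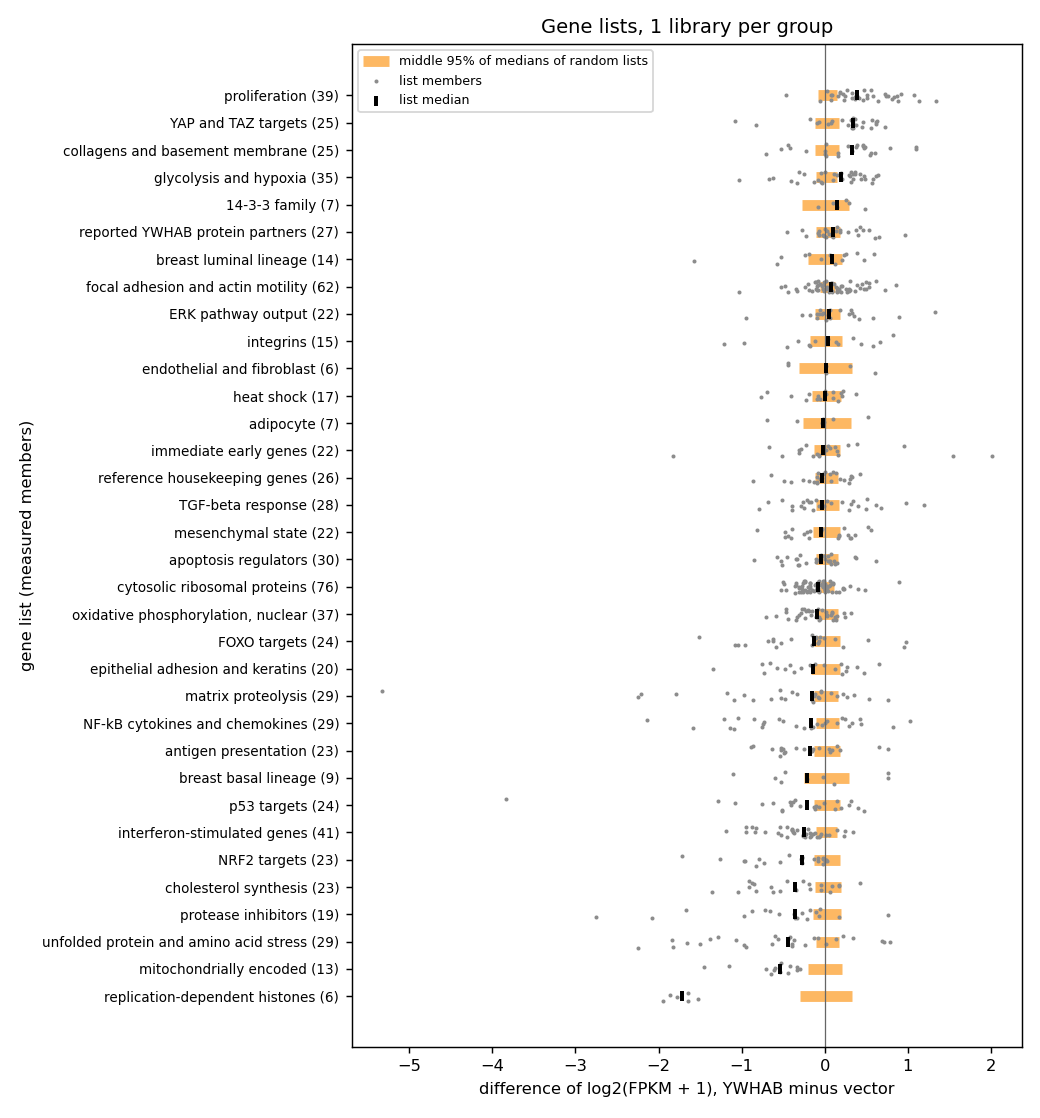
Members (grey points), medians (black bars) and the middle 95% of medians of 10000 random lists (orange) for the 34 lists with at least 5 measured members. The horizontal axis is the difference of log2(FPKM + 1), YWHAB minus vector; replication-dependent histones lie lowest at a median of -1.71 and proliferation genes highest at 0.39.

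Markers of other cell types were measured in part. Of 20 adipocyte markers 7 were measured, 0 passed the rule and the median was -0.02 (percentile 33.6), a sign that turned with rescaling to equal totals. AGPAT2, a lipid synthesis enzyme, was at 65.1 and 69.7 FPKM, PPARG at 19.8 and 15.5 and LPL, lipoprotein lipase, at 9.32 and 5.38, while ADIPOQ and LEP were listed at 0. Of 23 retina markers 2 were measured, ROM1 (3.79 and 1.91 FPKM) and RBPMS (11.3 and 7.17 FPKM), with a median of -0.65, and SAG and CRX were listed at 0. ROM1 shares 24.8% of its exon bases with EML3 on the opposite strand. The 1 leukocyte marker measured, CD14, was at 2.71 and 2.06 FPKM. Endothelial and fibroblast markers had 6 measured members, 0 past the rule and a median of 0.02 (percentile 48.1) that turned negative with the median ratio set to 0 and with no filter. COL1A1 was at 27.3 and 19.8 FPKM. Among 14 breast luminal markers AGR2 (3.44 and 0.497 FPKM) was the 1 member 2-fold lower, and the median was 0.09 with a mean of -0.06 (percentile 77.8), turning to -0.04 (percentile 27.1) with no filter. Among 9 basal markers keratin KRT17 (2.78 and 0.754 FPKM) was 2-fold lower, whereas CAV1 was at 94.2 and 161 FPKM and EGFR at 69.5 and 118. The basal median was -0.21 (percentile 4.02), and the list crossed to percentile 0.47 after length and GC correction (median -0.35), 1.53 against random lists matched on length too, 1.67 with rescaling to equal totals and 1.87 with no filter. Over members with a mean of at least 5 FPKM the median turned to 0.04.

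Of the 34 lists with a percentile, 13 stood apart below and 4 above, where 1.7 would fall outside if genes were drawn independently. After length and GC correction 12 and 4 of these stood apart. Genes of a list can vary together, which independent draws do not copy, so more than 1.7 may fall outside between any 2 libraries. The lists share members, so they are not independent counts, and with 1 library per group none of these differences has a replicate check.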

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

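The length and GC correction, the length-matched lists, the counting interval and the minimum of 50 fragments were chosen after seeing the data. The YWHAB log2 difference stayed between 0.4472 and 0.531 and stayed under the 2-fold rule. The number of genes at least 2-fold higher with YWHAB, 92 in the main setting, was 155 with no filter, 222 with a pseudocount of 0.1, 173 with rescaling to equal totals, 40 with a mean of at least 5 FPKM, 34 in protein-coding genes, 60 with a counting interval that excludes equal levels and 42 with at least 50 fragments. The number of genes at least 2-fold lower with YWHAB, 265 in the main setting, was 471 with a pseudocount of 0.1, 112 with a mean of at least 5 FPKM and 167 in protein-coding genes. Filters remove genes and a lower pseudocount widens differences of low genes by construction. Rescaling raised the FPKM of both libraries while the pseudocount and the filter stayed fixed. It therefore acts partly like a lower pseudocount and a looser filter, with 14435 genes compared against 13420 in the main setting. Lower genes made up 74.2% of the 2-fold genes, and from 66.8% to 83.1% over the alternatives. The median log2 difference of epithelial adhesion and keratins stood apart at -0.1958 after length and GC correction, -0.1355 with no filter and -0.1451 with rescaling to equal totals; the cause was not tested. The matrix proteolysis list stood apart in each alternative run. Of 67 named genes past the 2-fold rule, 67 stayed past it in each alternative fixed beforehand but the mean of at least 5 FPKM, which left 53 and kept 53. The filters and the protein-coding restriction leave a gene's difference unchanged, and a pseudocount of 0.1 can only widen it. These could not undo a call. After length and GC correction 62 stayed past the rule and 0 of the 67 changed sign. The others fell just short, for example COL6A3 at 0.9441 and MT-ND3 at -0.9804. No paired analysis was possible because each group has 1 library. The counting interval excluded equal levels for 60 of the 92 higher and 235 of the 265 lower genes. It did so for all 34 higher and 167 lower protein-coding genes. In the short RNA classes it did so for only 10 of 38 higher and 6 of 31 lower genes, and in the remaining classes for 16 of 20 and 62 of 67.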

Other observations

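The counting tests and the tests by number of libraries, the gene families and the shares of copied genes were chosen after the results were seen. Pregnancy-specific glycoprotein genes, a placental gene cluster on chromosome 19, were lower as a family. All 8 measured members were 2-fold lower, and fragments over the 10 members above 0 numbered 1476 in the vector library and 167 in the YWHAB library, a ratio of 0.101 (counting interval 0.0859 to 0.119). PSG7 had 70 fragments in the vector library and 0 in the YWHAB library. The members resemble each other, so the split among them is uncertain. The nuclear long noncoding RNA NEAT1 was at 96.6 and 49.9 FPKM and MALAT1 at 305 and 255 FPKM, and the noncoding LINC02154 was at 13.4 and 1.03 FPKM. The 2 mitochondrial ribosomal RNAs together had a ratio of 0.572. The chemokine gene CCL3L1, which also has close copies, had 335 and 71 fragments.

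Genes with near-identical copies were counted because HIST2H2AA4, HIST2H4B, XAGE1B and SERF1B were among the lowest genes, and those 4 are in the count. Of 99 protein-coding genes that share at least 50% of their sampled 50-mers with another place in the genome, 7 were 2-fold lower (7.07%, exact 95% interval 2.89% to 14.03%) and 1 was higher. Without HIST, PSG and XAGE genes 3 of 94 were lower (3.19%, exact 95% interval 0.66% to 9.04%) and 1 was higher. No 2-fold lower PSG gene reached the share of 50%, so the lower genes left out were HIST and XAGE genes. Of 8854 genes that share under 1%, 114 were lower (1.29%). Because the count includes the genes that prompted it, the shares are given as values only.

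Lower unfolded protein and amino acid stress genes in the YWHAB library were weighed against 3 explanations. A trend between the libraries with mean annotated transcript length and GC content is argued against, since after correction the list median still lay at percentile 0. A trend with the length of the transcripts expressed was not tested. Counting noise in single libraries is argued against too. The counting interval lay below equal levels for 69.0% of all 29 measured members (20) and above for 5. Counting error alone would place about 2.5% on each side. Intervals that exclude equal levels were also common elsewhere: of 26 housekeeping genes 10 lay above and 9 below. Excluding equal levels is therefore not particular to this list, and the shares bear on counting error only. Of the explanations weighed, the culture state of 1 dish per group stays open, because 1 library per group cannot separate the dish from YWHAB. Other differences between the 2 libraries were not weighed. The drop may therefore reflect YWHAB, how the vector dish was grown, or another difference between the libraries.

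Higher proliferation genes were weighed in the same way. After length and GC correction the list median lay at percentile 100, which argues against a trend with mean annotated transcript length and GC content. A trend with the length of the transcripts expressed was not tested here either. The growth state of 1 dish per group stays open with 1 library per group, so a difference in density or growth phase could give the same picture.

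YWHAB was only modestly higher in the library labelled as over-expressing it. Counting noise in single libraries is argued against, since the lower bound of the counting interval of the ratio was 1.36. Ordinary spread between 2 libraries stays open: 4.8% of the 500 genes nearest in mean FPKM were as far above the vector library, between the 1% and 5% set beforehand as deciding. Over all genes compared the share was 8.01%. The YWHAB transcript level alone therefore cannot tell whether the construct was active, and YWHAB protein was not measured here.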
